A study of Schizosaccharomyces pombe with 9 samples.

How the data were processed

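Poly(A) RNA selected with oligo(dT), per the labels' protocols, was sequenced from 9 fission yeast libraries: 3 of wild type (WT), 3 of the htb1-E112K strain (E112K) and 3 of the E112K clr6-1 strain. Samples were assigned to groups from the labels alone. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The biological coefficient of variation fitted over them was 0.0389. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom of 2.96 to 9.70 between pairs, so none was counted as a repeat deposit of another.

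The submitters' processing notes name fastp, Bowtie2, HISAT2, StringTie, RSEM and DESeq2, without versions or the step each was used for. The genome build, the annotation and the counting strand are not given in the sources used here. Per the file headers, the deposited tables hold a count per gene and library, which are whole numbers. If they came from RSEM they are estimates rounded before deposit. The authors also give FPKM per gene and library, which within a gene was proportional to its counts and was used only to check the tables (largest deviation 9.81% over 4166 genes with enough counts). The authors' log2 fold changes equal the log2 ratio of their mean FPKM, and their p-value and FDR columns, per the file headers, belong to their own test. Both were used only to describe the authors' deposited table, which lists 470 genes for E112K (356 higher, 114 lower) and 683 for E112K clr6-1 (504 higher, 179 lower) at an FDR under 0.05 and an absolute log2 fold change of at least 1. Each of the full deposited tables lists 5212 genes, of which 76 carry identifiers of assembled transcripts, some of them with a symbol or process terms in the deposited tables, and 59 have no symbol. The WT counts are identical in both full tables. Every per-library column was mapped to a library, and no row is a total or an unassigned class. Identifiers of 5109 genes matched the ASM294v3 reference annotation and 27 did not. Because the authors' build is not named, that reference served only for names, neighbours, overlaps and distance classes, and no coordinates are printed.

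Counts of all 9 libraries were fitted together with edgeR 4.0.16 (quasi-likelihood test, TMM normalization with factors from 0.987 to 1.025, the filterByExpr count filter, prior degrees of freedom 6.36) in R 4.3.3, and 3 contrasts were tested: E112K against WT, E112K clr6-1 against WT and E112K clr6-1 against E112K. Genes with a Benjamini-Hochberg adjusted p under 0.05 over 5119 tested genes were called. A gene at 0 in every library of a group has no fold change; its bound was computed against a floor of 3 counts over the group, which covers counting error only. With 16469576 to 20013351 counts per library, precision was tested on simulated data of 5119 genes, with 50 genes changed at each of 1.25, 1.5, 2 and 4-fold. In the setting of E112K against WT, 92% of 1.25-fold changes, 96% of 1.5-fold changes and all larger ones were recovered, with 0.12% of unchanged genes called. For E112K clr6-1 against WT the simulation recovered 98% at 1.25-fold, 94% at 1.5-fold, 96% at 2-fold and all at 4-fold, with 0.18% of unchanged genes called. For E112K clr6-1 against E112K it recovered 84% at 1.25-fold and all larger ones, with 0.22%. Most genes were unchanged in these simulations, whereas 3914 to 4286 of 5119 genes were called in the data. An adjusted p threshold admits more unchanged genes when most genes are called, so these shares of unchanged genes called do not carry over.

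Before the data were examined, 37 gene lists were fixed, of which 35 had at least 4 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over lists within a comparison, and the number of members past the test was counted over all genes and adjusted over the list alone. A raised list was called in each of the 3 simulations and 0 of 30 unchanged lists was. Genes were drawn independently there, so the simulations do not test how camera behaves when the genes of a list are correlated. The symbol ssp1 in the protein folding list turned out to name a protein kinase; the list was kept as fixed and also tested without it. Genes named in the text follow a rule fixed beforehand: for each comparison the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, groups that do not overlap and at least 5 CPM in the higher group; for each list described, up to 4 members with the smallest adjusted p; htb1, clr6 and the other core histone genes; and the markers ura4, leu1, ade6 and his3 with the mating-type cassette genes. Neighbours of mat1-Mc and sets from the gene ontology enrichment were named after their values were seen.

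For overlaps between comparisons that share libraries, 20 simulations of unchanged groups gave the value expected without any effect. The alternatives were RLE and upper-quartile normalization, no count filter, a mean of at least 5 CPM, DESeq2 1.42.0, a fit of the 6 libraries compared, a replicate block, a 2-fold minimum, removal of the 20 most abundant genes, leaving out each library in turn, and for lists an estimated correlation, fry, a replicate block and a subtelomeric list by position within 50 kb. Alternatives without assembled transcripts and genes at 0 in a group, and without ssp1, were added after the data were seen. Similar gene copies were found with BLAST 2.17.0 (at least 90% identity over at least 50% of the length), intervals are 95% bootstrap intervals from 10000 resamples, and other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.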

Results

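Poly(A) RNA of the fission yeast Schizosaccharomyces pombe was measured by RNA sequencing in 9 libraries that fall into 3 groups of 3: wild type (WT), a strain in which the histone H2B gene htb1 carries the E112K substitution (E112K), and a strain that carries the same substitution together with clr6-1, an allele of the class I histone deacetylase gene clr6 (E112K clr6-1). The WT libraries held 19597394, 17795867 and 18086600 counts, the E112K libraries 16469576, 17509325 and 19217624, and the E112K clr6-1 libraries 20013351, 17804992 and 17456781. The full tables listed 5212 genes, of which 5119 had enough counts to be tested. Levels are given as CPM, counts scaled to a common library size, with the SD over 3 libraries of a group. Adjusted p-values for genes are those of edgeR's quasi-likelihood test. The 20 most abundant genes took 9.87 to 10.8% of the counts in WT, 11.3 to 11.8% in E112K and 13.4 to 13.8% in E112K clr6-1. Ribosomal protein genes took at least 10.85% of the counts in WT, 8.44 to 8.81% in E112K and 9.08 to 9.57% in E112K clr6-1.

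The mutated genes were read first. Transcripts of htb1 (SPCC622.09), the H2B gene, stood at 1669 ± 43.0 CPM in WT, 5131 ± 127 CPM in E112K and 5435 ± 119 CPM in E112K clr6-1 (SD, n = 3). The rise over WT was 3.07-fold in E112K (adjusted p = 9.34e-13) and 3.26-fold in E112K clr6-1 (adjusted p = 4.59e-13). Between the mutant strains htb1 differed by 0.08 on the log2 scale and did not pass the test (adjusted p = 0.0614), although DESeq2 and 4 other alternatives called it higher in E112K clr6-1. The neighbouring H2A gene hta1 was measured at 363 ± 3.66 CPM in WT, 404 ± 18.5 CPM in E112K and 361 ± 6.58 CPM in E112K clr6-1. Transcripts of clr6 (SPBC36.05c) fell from 142 ± 7.08 CPM in WT to 87.1 ± 1.77 CPM in E112K, where they fell by 0.71 on the log2 scale (adjusted p = 2.35e-09), and to 119 ± 1.47 CPM in E112K clr6-1, where they fell by 0.26 (adjusted p = 2.36e-05). These transcript levels do not show whether a library carries the htb1 or clr6-1 point mutations, and the labels do not say whether the mutant strains carry a further copy of htb1 or a marker at its locus.

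Against WT, the other core histone genes moved less than htb1. The H2A gene hta2 fell from 922 ± 27.6 CPM in WT to 747 ± 21.9 CPM in E112K and 709 ± 13.8 CPM in E112K clr6-1. Of the H3 and H4 genes, hht1 and hhf1 fell by 0.25 and 0.26 on the log2 scale in E112K, while hht2, hht3, hhf2 and hhf3 did not pass the test there. In E112K clr6-1 against WT, hhf2 rose 1.28-fold and hht2 rose 1.14-fold, whereas hht3 fell by 0.22 and hhf3 by 0.25. Transcripts of cnp1, which encodes the centromeric H3 variant CENP-A, fell from 33.2 ± 2.34 CPM in WT to 25.4 ± 0.974 CPM in E112K (adjusted p = 6.77e-05) and stood at 68.7 ± 1.35 CPM in E112K clr6-1, 2.07-fold above WT (adjusted p = 1.09e-09). The H2A.Z gene pht1 was at 148 ± 2.63, 141 ± 1.55 and 156 ± 5.59 CPM in WT, E112K and E112K clr6-1. As a list, the 11 core histone genes had 2 higher and 4 lower in E112K against WT, 5 higher and 5 lower in E112K clr6-1 against WT, and 6 higher and 3 lower in E112K clr6-1 against E112K (7 and 4 adjusted over the list alone); limma's camera called the list in none of them (adjusted p = 0.472, 0.904 and 0.495).

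Marker and mating-type genes differed between the groups. The marker gene ura4, which encodes orotidine-5'-phosphate decarboxylase, had 0 counts in every WT and E112K library and stood at 145 ± 1.93 CPM in E112K clr6-1, at least 2707-fold above WT and at least 2554-fold above E112K against a floor of 3 counts over the group. The mating-type cassette gene mat1-Mc had 2, 0 and 2 counts in the WT libraries, 0 in E112K, and 75.1 ± 3.3 CPM in E112K clr6-1, at least 1328-fold above E112K. Its call as lower in E112K than in WT (adjusted p = 0.0445) rests on those WT counts and was lost with DESeq2, with the replicate block and in several fits without a library. The markers leu1, his3 and ade6 fell in E112K by 0.34, 0.49 and 0.83 on the log2 scale and in E112K clr6-1 by 1.15, 1.10 and 0.39. The fixed list of 8 auxotrophic markers had 7 genes lower in E112K (adjusted p = 0.00503 in camera; adjusted p = 0.29 with an estimated correlation). In E112K clr6-1 against WT, 7 were lower and 1, ura4, was higher (adjusted p = 0.0354; adjusted p = 0.415 with an estimated correlation); the median of -0.81 and the mean of 1.03 on the log2 scale differ in sign there.

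**Figure D1:**
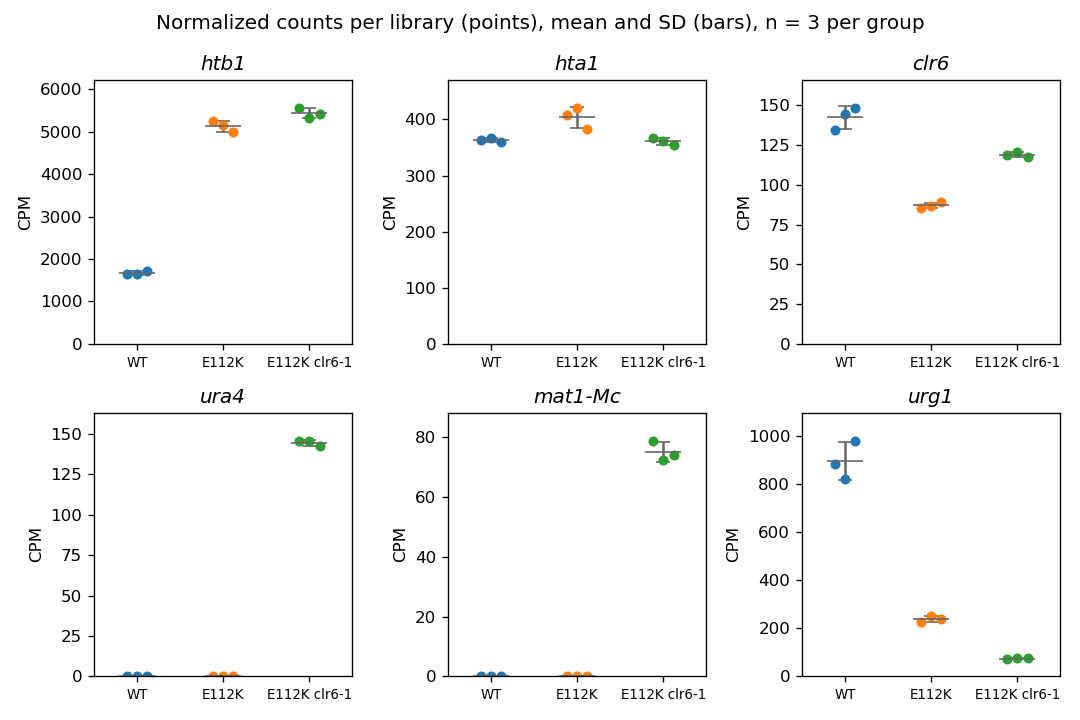
Level in CPM (y axis, from 0) of htb1, hta1, clr6, ura4, mat1-Mc and urg1 in each library of WT, E112K and E112K clr6-1; points are libraries, grey bars the mean and SD (n = 3). Transcripts of htb1 were at a mean of 1669 CPM in WT, 5131 CPM in E112K and 5435 CPM in E112K clr6-1, and ura4 and mat1-Mc were high in E112K clr6-1 alone.

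The first comparison, E112K against WT, asked how transcript levels in the strain with the H2B substitution differed from WT. Transcripts of htb1 itself went from 1669 CPM in WT to 5131 CPM in E112K, and the labels do not give the rest of the genotype. The comparison thus cannot be shown to isolate the substitution. Of the core stress-induced genes 24 of 25 rose, as did 11 of 13 iron-uptake genes and 65 of 87 subtelomeric genes, while most ribosomal protein genes, 37 of 45 amino acid biosynthesis genes and 10 of 14 sterol and Sre1-linked genes fell. Limma's camera called each of these lists, but 0 of its 13 list calls held with an estimated correlation (smallest adjusted p = 0.055; 4 lists at an unadjusted p under 0.05). The small heat-shock protein gene hsp16 rose 49.5-fold to 1038 ± 59.6 CPM (SD, n = 3), and the heme transporter gene str3 rose from 3.16 ± 0.779 to 298 ± 29.7 CPM (94.0-fold). Transcripts of hem13, which encodes coproporphyrinogen oxidase of heme synthesis, fell by 2.19 on the log2 scale, from 1107 ± 10.2 to 242 ± 6.43 CPM. In all, 3914 of 5119 genes passed the test, 1923 higher and 1991 lower, and 475 of them changed at least 2-fold, 367 higher and 108 lower. The median absolute log2 fold change was 0.27. The libraries of the groups did not overlap for 3991 genes (78% of those tested), where chance gives 10%.

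Most of the largest rises were of genes without a count in WT. With 0 counts in every WT library, mug108 (SPAC29A4.12c) reached 68.3 ± 3.93 CPM in E112K, at least 1279-fold above the floor of 3 counts over the WT group. The same bound was 371-fold for SPBC18A7.01, 314-fold for mde5 (SPAC25H1.09), an alpha-amylase homolog, 244-fold for cum1 (SPAC22G7.11c), 218-fold for mug143 (SPAC167.06c), 211-fold for dam1 (SPAC589.08c), a subunit of the kinetochore DASH complex, and 181-fold for SPAC4F10.17. All but SPAC4F10.17 overlap another annotated gene. SPAC186.02c was at 40.2 ± 1.97 CPM in E112K and 0.0168 ± 0.029 CPM in WT. Among the falls, SPBC1683.06c, a predicted uridine ribohydrolase gene that also overlaps another gene, went from 77.3 ± 3.12 CPM to 0 counts, at least 1365-fold lower. The neighbours SPAC750.05c and SPAC750.06c fell by 5.39 and 3.98 on the log2 scale. The assembled transcript MSTRG.122, the predicted uracil phosphoribosyltransferase gene SPAC1399.04c, msa1 and SPAC3G6.05 had log2 changes of -3.25, -2.64, -2.36 and -2.12.

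Of 25 core stress-induced genes, 24 rose and 1 did not pass the test, with a median of 3.38-fold (camera adjusted p = 6.21e-10; adjusted p = 0.179 with an estimated correlation). The metallothionein gene zym1 rose 27.3-fold, the heat-shock protein gene hsp9 rose 17.7-fold to 2372 ± 56.2 CPM, and the neutral trehalase gene ntp1 rose 5.15-fold. Among 22 genes of the protein folding list 17 rose and 3 fell (adjusted p = 0.000488; adjusted p = 0.42 with an estimated correlation), and 18 rose adjusted over the list alone. The Hsp70 gene ssa1 rose 14.6-fold, and the co-chaperone genes sti1 and wos2 rose 2.96-fold and 2.61-fold; the mitochondrial chaperone gene SPBC4F6.17c rose 2.49-fold. Iron-uptake genes rose in 11 of 13 cases and fell in 2 (adjusted p = 0.00119; adjusted p = 0.29 with an estimated correlation). Besides str3, the heme receptor gene shu1 rose 210-fold from 0.339 ± 0.0417 CPM, the ferric reductase gene frp1 rose 13.4-fold and the multicopper oxidase gene fio1 rose 7.76-fold.

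Of 87 subtelomeric genes tested, 65 rose, 14 fell and 8 did not pass, with a median of 2.82-fold (adjusted p = 3.81e-08; adjusted p = 0.055 with an estimated correlation). SPBPB21E7.04c rose 94.5-fold to 631 ± 14.7 CPM, the enolase gene eno102 rose 23.2-fold, grt1 rose 15.0-fold and pfl9, which encodes a flocculin-type cell-surface glycoprotein, rose 14.1-fold. By distance from the nearer end of chromosome I or II, 76.4% of 55 genes within 50 kb and 62.7% of 59 genes between 50 and 100 kb changed at least 2-fold, against 6.7% of 3384 genes beyond 500 kb. Of 20 wtf genes, a family of meiotic drivers, 13 rose and 3 fell (adjusted p = 0.0104; adjusted p = 0.29 with an estimated correlation). Of these, wtf20, wtf6, wtf18 and wtf7 rose 2.56-, 2.44-, 2.31- and 2.29-fold. Meiosis and sporulation genes rose in 20 of 35 cases and fell in 4 (adjusted p = 0.0138; adjusted p = 0.196 with an estimated correlation), with 19 higher adjusted over the list alone. The RNA-binding regulator gene mei2 rose 6.97-fold, the transcription factor gene ste11 rose 4.41-fold, the recombinase gene dmc1 rose 3.07-fold and isp3 rose 2.21-fold. The P-cell genes sxa1, map2, map3 and map4 rose 1.48-, 1.55-, 1.46- and 1.17-fold. These are all 4 of their list (adjusted p = 0.0292; adjusted p = 0.374 with an estimated correlation). Flocculin genes rose in 8 of 10 cases (adjusted p = 0.0153; adjusted p = 0.296 with an estimated correlation), with pfl6 up 3.71-fold and its family member pfl3 lower by a log2 change of -1.35. Ribosome biogenesis genes rose in 38 of 68 cases and fell in 18 (adjusted p = 0.0245; adjusted p = 0.653 with an estimated correlation), for example utp14 by 1.78-fold and kri1 by 1.64-fold.

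**Figure D2:**
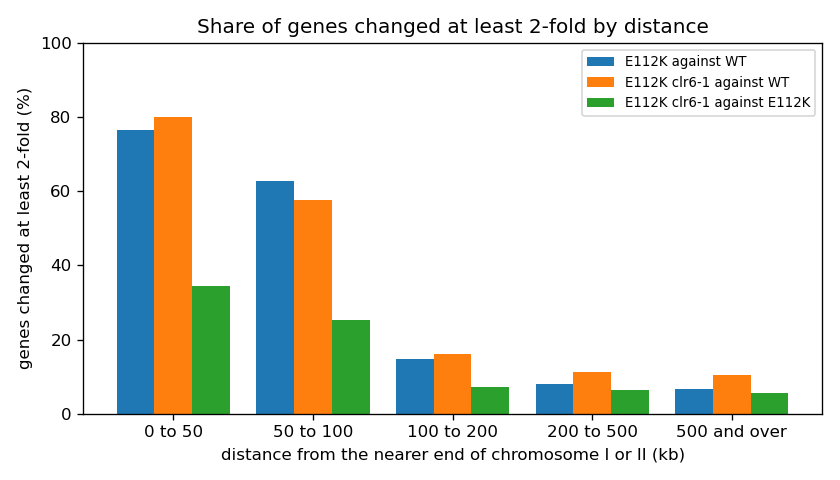
Percent of genes changed at least 2-fold (y axis) in bins of distance in kb from the nearer end of chromosome I or II (x axis), one bar per comparison. In E112K against WT the share was 76.4% within 50 kb and 6.7% beyond 500 kb.

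Among the lists that fell, ribosomal protein genes had 1 of 131 higher, 18 that did not pass and the rest lower, with a median log2 fold change of -0.31 (adjusted p = 3.08e-12; adjusted p = 0.42 with an estimated correlation). Transcripts of rpl1603 fell by 1.87 on the log2 scale, of rpl1002 by 0.86, of rpl803 by 0.76 and of rps1402 by 0.73. Amino acid biosynthesis genes fell in 37 of 45 cases and rose in 1 (adjusted p = 2.33e-07; adjusted p = 0.29 with an estimated correlation). Transcripts of arg12, the argininosuccinate synthase gene, went from 832 ± 33.8 to 372 ± 3.71 CPM, and his1, his2 and arg4 had log2 changes of -0.80, -0.70 and -0.80. Sterol and Sre1-linked genes fell in 10 of 14 cases and rose in 2 (adjusted p = 0.0104; adjusted p = 0.29 with an estimated correlation), with erg31, erg1 and sre1 lower by log2 changes of -1.97, -1.52 and -0.94. The mitochondrially encoded genes, whose share of the counts was 0.0003% in each WT library and 0.0017 to 0.0026% in E112K, had 4 of 5 tested members higher, cox3 by 7.66-fold and cob1 by 4.93-fold, but their list was not called (adjusted p = 0.107).

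The lists closest to the study's question about genome stability were not called. Of 50 DNA damage and repair genes 23 rose and 15 fell (adjusted p = 0.377), among them rad50 at 1.77-fold and ctp1, the CtIP homolog, at 1.83-fold. Of 34 DNA replication genes 8 rose and 18 fell (adjusted p = 0.135), including mcm7 with a log2 change of -0.72. Of 32 kinetochore, cohesin and checkpoint genes 6 rose and 16 fell (adjusted p = 0.147), with 5 higher adjusted over the list alone. Transcripts of cnp3, the CENP-C gene, fell from 211 ± 6.94 to 85.7 ± 1.95 CPM. Of 34 heterochromatin factors 11 rose and 9 fell (adjusted p = 0.94), with 8 lower adjusted over the list alone, and of 18 subunits of Clr6 complexes 7 rose and 9 fell (adjusted p = 0.382). The 11 Tf2 retrotransposon genes tested had 1 higher and 8 lower (adjusted p = 0.109); their median log2 fold change of -0.34 and mean of 0.59 differ in sign. Tf2-4 was at 0.107 ± 0.00563 CPM in WT and 125 ± 53.4 CPM in E112K, Tf2-2 fell by 0.54 on the log2 scale, and Tf2-3 and Tf2-6 have equal values in every group. For the other lists described in this comparison the counts adjusted over the list alone were the same.

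Camera called 13 of 35 lists here, 9 higher and 4 lower; with an estimated correlation between genes it called 0, and 4 had an unadjusted p under 0.05. Median and mean log2 fold change also differed in sign, around 0, for the core histones (-0.06 and 0.04, camera lower), the heterochromatin factors (-0.02 and 0.01, camera lower) and the mitotic genes (0.01 and -0.06, camera lower). The counting strand is not given in the sources used here, so overlapping genes, antisense pairs and near-identical copies (wtf, Tf2, paired histone and ribosomal protein genes) are uncertain.

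**Figure D3:**
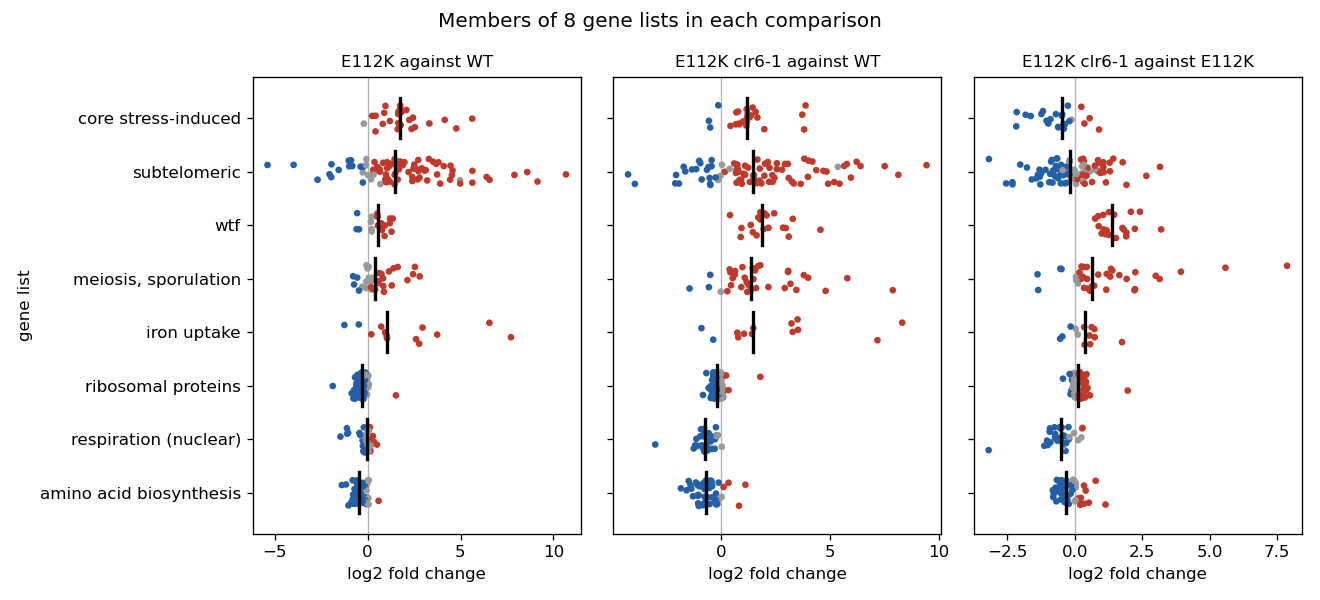
Log2 fold change (x axis) of each tested member of 8 gene lists (y axis) in the 3 comparisons; red points passed the test as higher, blue as lower, grey did not pass, and black bars are list medians. Core stress-induced genes had a median of 1.76 in E112K against WT and of -0.48 in E112K clr6-1 against E112K, and wtf genes a median of 1.89 in E112K clr6-1 against WT.

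The second comparison set the strain with both mutations, E112K clr6-1, against WT. These groups also differed in transcripts of ura4 and mat1-Mc, and the labels do not say whether the strains differ in genotype beyond the mutations. The comparison thus cannot be shown to isolate the mutations. Of the meiosis and sporulation genes 31 of 35 rose, as did all 20 wtf genes and 13 of 15 hexose transport and gluconeogenesis genes, while 28 of 32 nuclear genes of respiration and 39 of 45 amino acid biosynthesis genes fell. Limma's camera called each of these lists, and with an estimated correlation the meiosis list kept its call (adjusted p = 0.0387) and the others named lost theirs (adjusted p from 0.0678 to 0.503). The endoglucanase gene eng2 rose from 114 ± 6.12 to 1822 ± 40.2 CPM (SD, n = 3), wtf20 rose from 5.17 ± 0.363 to 122 ± 2.05 CPM (23.6-fold) and str3 rose to 1006 ± 63.4 CPM (317-fold). The uracil-regulated genes urg1, which encodes a GTP cyclohydrolase, and urg2 fell by 3.59 and 3.88 on the log2 scale, from 896 ± 80.3 to 74.2 ± 1.87 CPM and from 754 ± 41.9 to 51.2 ± 1.49 CPM. In E112K, where ura4 was at 0 as in WT, urg1 and urg2 stood at 238 ± 11.5 and 201 ± 7.77 CPM and had fallen by 1.91 each. In all, 4286 genes passed the test, 2137 higher and 2149 lower, and 682 changed at least 2-fold, 516 higher and 166 lower. The libraries did not overlap for 4340 genes (84.8%, where chance gives 10%).

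After ura4, the largest rises were again of genes at 0 in WT, and mug108, mde5, SPBC4F6.11c, mug143, dam1, SPBC336.05c and SPBC18A7.01 were at least 604-, 388-, 335-, 207-, 194-, 167- and 152-fold higher against the floor of 3 counts over the group. SPBC336.05c and mde5 varied most between libraries, at 8.9 ± 5.48 and 20.7 ± 7.14 CPM. All 7 overlap another annotated gene. SPBC1683.06c and bag101, a BAG-family chaperone regulator gene, went from 77.3 ± 3.12 and 74.8 ± 5.01 CPM in WT to 0 counts, at least 1411-fold and 1367-fold lower; both overlap another gene. SPBC27B12.09c, SPAC186.06, SPAC750.05c and SPBC26H8.11c had log2 changes of -5.02, -4.27, -3.96 and -3.29.

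All 20 wtf genes rose, with a median of 3.71-fold (camera adjusted p = 2.57e-07; adjusted p = 0.0678 with an estimated correlation); wtf18 rose 9.77-fold, wtf6 rose 8.59-fold and wtf5 rose 3.55-fold. Meiosis and sporulation genes rose in 31 of 35 cases and fell in 3, with a median of 2.58-fold, and theirs was the 1 list that kept its call (adjusted p = 3.44e-06; adjusted p = 0.0387 with an estimated correlation). The forespore membrane gene meu14 rose 9.08-fold, spo6 rose 8.45-fold and isp3 rose 8.41-fold. All 7 M-cell genes rose (adjusted p = 0.00196; adjusted p = 0.145 with an estimated correlation). Among them were the M-factor pheromone genes mfm2, by 142-fold from 2.25 ± 0.478 CPM, and mfm1, from 0.876 ± 0.2 to 19.3 ± 0.826 CPM, and the pheromone transporter gene mam1, by 1.75-fold. The 4 P-cell genes had 2 higher and 1 lower (adjusted p = 0.569). Of 18 targets of the G1/S transcription factor MBF 13 rose and 1 fell (adjusted p = 0.0179; adjusted p = 0.569 with an estimated correlation), with ctp1 up 3.84-fold, the dUTPase gene dut1 up 2.27-fold and the ribonucleotide reductase gene cdc22 up 1.60-fold.

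Subtelomeric genes rose in 62 of 87 cases and fell in 20, with a median of 2.80-fold (adjusted p = 2.9e-05; adjusted p = 0.0678 with an estimated correlation); grt1 rose 16.1-fold and SPBPB21E7.04c rose 50.3-fold. Core stress-induced genes rose in 22 of 25 cases and fell in 3 (adjusted p = 1.61e-05; adjusted p = 0.281 with an estimated correlation), with srx1, the sulfiredoxin gene, up 14.7-fold and hsp16 up 14.0-fold. Of the protein folding list 17 rose and 4 fell (adjusted p = 0.00196; adjusted p = 0.569 with an estimated correlation), with sti1 up 3.62-fold and ssa1 up 4.27-fold. One member listed as ssp1 matched a protein kinase gene rather than a chaperone, at 303 ± 10.8 CPM in WT and 894 ± 32.2 CPM in E112K clr6-1. Iron-uptake genes rose in 11 of 13 cases and fell in 2 (adjusted p = 0.00108; adjusted p = 0.29 with an estimated correlation), with fio1 up 11.5-fold and the siderophore synthesis gene sib1 up 2.66-fold. Hexose transport and gluconeogenesis genes rose in 13 of 15 cases (adjusted p = 0.00108; adjusted p = 0.415 with an estimated correlation). The transporter genes ght7 and ght3 rose 30.1-fold and 27.7-fold, and ght8 had a log2 change of -1.87. Glycolysis genes rose in 15 of 18 cases and fell in 1 (adjusted p = 0.00141; adjusted p = 0.569 with an estimated correlation), with gpd3 up 3.81-fold and the phosphofructokinase gene pfk1 going from 2024 ± 82.7 to 4117 ± 99.3 CPM. Flocculin genes rose in 9 of 10 cases (adjusted p = 0.0129; adjusted p = 0.341 with an estimated correlation), and ribosome biogenesis genes rose in 42 of 68 and fell in 17 (adjusted p = 0.0086; adjusted p = 0.742 with an estimated correlation), utp20 by 3.27-fold.

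Of 32 nuclear genes of respiration 28 fell, 0 rose and 4 did not pass, with a median log2 fold change of -0.74 (adjusted p = 5.29e-06; adjusted p = 0.503 with an estimated correlation). The cytochrome oxidase gene cox4 fell by 1.13 on the log2 scale, the ATP synthase genes atp16 and atp4 by 0.95 and 0.79 and the complex III gene qcr2 by 0.88. Amino acid biosynthesis genes fell in 39 of 45 cases and rose in 4 (adjusted p = 2.27e-07; adjusted p = 0.29 with an estimated correlation), with arg12 lower by a log2 change of -1.84, arg4 by -1.58 and his2 by -1.36. Ribosomal protein genes fell in 91 of 131 cases and rose in 6, with a median log2 fold change of -0.17 (adjusted p = 6.06e-06; adjusted p = 0.612 with an estimated correlation). Transcripts of rpl102 fell by 0.83 and of rpl1702 by 0.68, while rps1401 rose 3.48-fold. DNA damage and repair genes had 31 of 50 higher and 14 lower without a list call (adjusted p = 0.116). They include the checkpoint kinase genes tel1, which rose from 69.8 ± 3.58 to 147 ± 1.38 CPM, and rad3, which rose 1.86-fold, and nbs1, which rose 1.87-fold. Of the heterochromatin factors 18 of 34 rose and 11 fell (adjusted p = 0.569), with the H3K9 methyltransferase gene clr4 up 1.59-fold and clr2 and swi6 lower by log2 changes of -1.09 and -0.57.

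Camera called 16 lists here, 12 higher and 4 lower, and with an estimated correlation 1; 5 had an unadjusted p under 0.05 with that setting. Median and mean differed in sign for the core histones (-0.01 and 0.21, camera higher), the histone chaperone and H2B ubiquitylation genes (-0.02 and 0.05, camera lower), Tf2 genes (-0.11 and 0.63, camera lower), oxidative stress and efflux genes under Pap1 (-0.09 and 0.40, camera lower) and replication genes (0.004 and -0.04, camera lower). For the lists described, the counts adjusted over the list alone were the same as over all genes.

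The third comparison, E112K clr6-1 against E112K, asked how the strain with both mutations differed from the E112K strain. These groups, too, differed in transcripts of ura4 and mat1-Mc, and whether that goes with clr6-1 or with another difference in genotype is not known. The comparison thus cannot be shown to isolate the clr6-1 allele. Since a clr6-1 strain without E112K is not analysed here, no interaction between the mutations can be estimated. All 20 wtf genes, 28 of 35 meiosis and sporulation genes, 6 of 7 M-cell genes, 14 of 18 subunits of the Clr6 complexes and 15 of 18 MBF targets rose. Of 131 ribosomal protein genes 69 rose, 6 fell and 56 did not pass. Lower were 20 of 25 core stress-induced genes, 25 of 32 nuclear genes of respiration and 28 of 45 amino acid biosynthesis genes. Limma's camera called each of these 9 lists, and 0 of the calls held with an estimated correlation (adjusted p from 0.0673 to 0.759; 3 lists at an unadjusted p under 0.05). Transcripts of eng2 rose 15.3-fold from 119 ± 1.78 CPM (SD, n = 3), and wtf20 rose 9.22-fold from 13.2 ± 0.509 CPM. The stress genes hsp9 and ubi4, a polyubiquitin gene, fell from 2372 ± 56.2 to 528 ± 14.6 CPM and from 2374 ± 44.3 to 534 ± 52.1 CPM. In all, 4035 genes passed the test, 2060 higher and 1975 lower, and 374 changed at least 2-fold, 229 higher and 145 lower. The libraries did not overlap for 4120 genes (80.5%, where chance gives 10%).

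Next to ura4 and mat1-Mc, the largest rises were of SPBC4F6.11c, mde7, an RNA-binding protein gene, and SPBC336.05c, all at 0 in E112K and at least 316-, 231- and 157-fold higher against the floor of 3 counts over the group; each overlaps another gene. The pheromone gene mfm2 rose 224-fold from 1.44 ± 0.243 CPM, and the assembled transcripts MSTRG.3648 and MSTRG.3654 rose by 7.10 and 5.93 on the log2 scale. The genes bag101, ggt2, which encodes a gamma-glutamyltranspeptidase, and SPAC4F10.17 had 0 counts in E112K clr6-1 and were at least 1106-, 860- and 177-fold lower than in E112K, where they stood at 60.5 ± 7.16, 47.1 ± 3.65 and 9.66 ± 1.52 CPM. The complex III iron-sulphur protein gene rip1 fell by 3.19 on the log2 scale, from 124 ± 38.8 to 13.7 ± 3.83 CPM, and prl65, SPBC1289.14, SPMIT.06 and SPAC27E2.13 fell by 3.40, 2.92, 2.92 and 2.54. In the genes beside mat1-Mc, SPBC23G7.10c and mag2, rises of 4.77 and 4.41 on the log2 scale were measured, values looked at because of their position.

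All 20 wtf genes rose, with a median of 2.58-fold (camera adjusted p = 1.48e-07; adjusted p = 0.0673 with an estimated correlation), wtf10 by 4.69-fold and wtf18 by 4.23-fold. Meiosis and sporulation genes rose in 28 of 35 cases and fell in 4 (adjusted p = 0.000133; adjusted p = 0.0673 with an estimated correlation), spo6 by 4.71-fold and isp3 by 3.80-fold. M-cell genes rose in 6 of 7 cases (adjusted p = 0.0206; adjusted p = 0.414 with an estimated correlation), mfm1 by 7.99-fold, mam1 by 2.02-fold and the protease gene sxa2 by 1.76-fold. The P-cell genes map2, sxa1 and map3 fell by 0.81, 0.54 and 0.28 on the log2 scale and map4 rose 1.61-fold, without a call of their list (adjusted p = 0.359). Of 18 subunits of Clr6 complexes 14 rose and 2 fell (adjusted p = 0.00431; adjusted p = 0.414 with an estimated correlation), laf2 by 2.40-fold, sds3 by 2.28-fold and rxt3 by 2.15-fold, and clr6 itself rose 1.37-fold (adjusted p = 2.29e-07). Of the MBF targets 15 of 18 rose and 1 fell (adjusted p = 0.00478; adjusted p = 0.67 with an estimated correlation), with ctp1 up 2.09-fold. Ribosomal protein genes rose in 69 of 131 cases and fell in 6, with 67 higher adjusted over the list alone and a median log2 fold change of 0.12 (adjusted p = 0.00167; adjusted p = 0.759 with an estimated correlation); rpl1603 rose 3.91-fold.

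Of the core stress-induced genes 20 of 25 fell and 4 rose (adjusted p = 0.000493; adjusted p = 0.414 with an estimated correlation), hsp9 by a log2 change of -2.17, ubi4 by -2.15 and hsp16 by -1.82. Nuclear genes of respiration fell in 25 of 32 cases and rose in 1 (adjusted p = 0.000121; adjusted p = 0.67 with an estimated correlation), with the ATP synthase gene atp2 going from 1704 ± 92.3 to 837 ± 14.9 CPM. Amino acid biosynthesis genes fell in 28 of 45 cases and rose in 10 (adjusted p = 0.0105; adjusted p = 0.67 with an estimated correlation), leu1 by a log2 change of -0.81 and arg1 by -0.80, while cys2 rose 2.21-fold. The 5 mitochondrially encoded genes tested had 4 lower and a median log2 fold change of -2.30 at very low levels, cox1 going from 2.61 ± 0.406 to 0.523 ± 0.11 CPM; their list was not called (adjusted p = 0.0644) except with the replicate block (adjusted p = 0.05 after rounding). Subtelomeric genes went both ways, with 28 higher and 41 lower of 87 (adjusted p = 0.313), as did protein folding genes, with 9 higher and 9 lower (adjusted p = 0.992). The kinetochore gene cnp3 rose 3.06-fold to 262 ± 3.61 CPM and cnp1 rose 2.70-fold (adjusted p = 1.56e-10), in a kinetochore, cohesin and checkpoint list with 17 of 32 higher and 11 lower (adjusted p = 0.349). Camera called 9 lists, 6 higher and 3 lower, and with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05. Median and mean differed in sign for protein folding genes (0.04 and -0.03, camera lower), auxotrophic markers (-0.20 and 1.59, camera lower) and Tf2 genes (-0.004 and 0.04, camera higher).

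The changes of both mutant strains against WT were then set side by side. Among the genes that passed in both, 2699 moved in the same direction, 1320 higher and 1379 lower, where independent lists of these sizes would share 802.8 and 835.8; 660 moved in opposite directions, against 1638.5 for independent lists. At 2-fold or more, 285 were higher and 54 lower in both, against 37 and 3.5. Unchanged groups simulated against the same WT libraries shared 0.05 calls on average over 20 runs, but hardly any gene is called where no group differs. This value therefore does not show how many shared calls the same WT libraries add among groups that differ. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.81 where the shared controls alone gave 0.00552. The observed value includes genes at 0 in a group, whose fitted values are very large, such as 13.28 for mug108 in E112K against WT. The simulation was drawn from WT means and holds no such changes, so these covariances are not like for like. Pearson's r of 0.713 lay inside the simulated range of 0.312 to 0.722 (mean 0.538). The simulated groups held no change, so that range does not show what part of the observed r the shared controls gave. With 3 WT libraries the controls could not be split, so part of the excess of shared calls may come from the shared controls.

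Of the genes changed in E112K, 1861 moved back in E112K clr6-1, 930 that had risen and 931 that had fallen, while 1258 moved further in the same direction. A gene moved back if it was called in the opposite direction in E112K clr6-1 against E112K, whether or not it ended nearer WT. Against WT, 660 genes were called in opposite directions in the mutant strains, so the count does not measure a return to WT levels. The mutant strains also differ in transcripts of ura4 and mat1-Mc, and the labels do not say whether they differ in genotype beyond clr6-1. These moves therefore cannot be credited to clr6-1 alone. Independent lists would give 741.9 and 801.2 such reversals among the genes that had risen and fallen. Simulated unchanged groups gave 0, but hardly any gene is called where no group differs. That 0 therefore does not measure the reversals that shared E112K libraries could add among groups that differ. The covariance of E112K against WT with E112K clr6-1 against E112K was -0.15, and -0.0048 in the simulation of the shared E112K libraries. The observed value again includes genes at 0 in a group, such as SPAC4F10.17, and the simulation holds no such changes. These covariances are therefore not like for like. Pearson's r for this pair, -0.185, was closer to 0 than in any of 20 simulated runs, which gave -0.69 to -0.199 (mean -0.497). Those runs held no change between groups, so they do not show what part of this r the shared libraries gave. Of 367 genes at least 2-fold higher in E112K, among them hsp9 and ssa1, 170 moved back in E112K clr6-1 by the same rule. A further 124 moved further up, and 285 of the 367 were still at least 2-fold above WT. Of 108 at least 2-fold lower, 67 moved back by that rule, among them rpl1603 and cnp3, whether or not they passed the WT level. Another 28 moved further down, and 54 of the 108 were still at least 2-fold below WT. The median log2 fold change against WT of the higher set was 1.76 in E112K and 1.78 in E112K clr6-1, and that of the lower set was -1.37 and -0.99.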

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

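Of the alternatives, those without assembled transcripts and genes at 0 in a group (47 genes at 0) and the protein folding list without ssp1 were chosen after the data were seen. Genes called in E112K against WT, E112K clr6-1 against WT and E112K clr6-1 against E112K numbered 3914, 4286 and 4035. Without one library at a time they numbered 3749 to 3904, 4129 to 4308 and 3850 to 4109, and under the other settings of normalization, filter, tool and block 3815 to 3921, 4166 to 4296 and 3944 to 4063. The same-direction overlap of 2699 ranged from 2540 to 2681 and from 2604 to 2697, and the 1861 genes that moved back from 1749 to 1870 and from 1794 to 1878. Requiring an absolute log2 fold change of at least 1 left 475, 682, 374, 339 and 96 by construction, and the share of higher calls became 77.3, 75.7 and 61.2% from 49.1, 49.9 and 51.1%. With the replicate block 3876, 4267 and 4015 genes were called, 2676 overlapped and 1839 moved back. Same-numbered libraries did not deviate together in every pair (correlations from -0.17 to 0.18), nor did every library correlate best with its own number. Pairing by number was thus not shown, and with 3 libraries per group a weak shared effect cannot be excluded. Lists called numbered 13, 16 and 9. An estimated correlation left 0, 1 and 0 (at an unadjusted p under 0.05, 4, 5 and 3), the block gave 13, 16 and 10, and fry gave 31, 28 and 29, a test that by construction does not compare a list with other genes. Under fry the auxotrophic markers turned from lower to higher in E112K clr6-1 against WT (fry adjusted p = 1.97e-09). There 7 of the 8 markers were lower and ura4 alone was higher, and a test without ura4 was not run. Lists not called by camera also turned to higher under fry. These were the markers in E112K clr6-1 against E112K (fry adjusted p = 1.39e-09) and the core histones in E112K against WT (0.0253). In E112K clr6-1 against WT they were the Pap1 (0.0063) and histone chaperone (0.00161) lists. Without ssp1 the protein folding list gave adjusted p-values of 0.000299, 0.00427 and 0.817. No called list's median changed sign under RLE, upper-quartile normalization or removal of the 20 most abundant genes. Of 476 results for named genes 0 were reversed, and 13 changed their call in any of 18 alternatives other than the fold minimum. These were htb1, hta2, hht1, cuf1 and pho7 in E112K clr6-1 against E112K, cox3, SPMIT.06, ctr6, hhf1 and pht1 in E112K clr6-1 against WT, and mat1-Mc, hht2 and pht1 in E112K against WT. Pseudocount and filter alternatives for FPKM were not run because counts were given. Depth limits what can be said of genes near 0, such as cox1 at 0.523 ± 0.11 CPM in E112K clr6-1.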

Other observations

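The gene ontology enrichment, the test of mating type, the alternative without assembled transcripts and genes at 0 in a group, and the protein folding list without ssp1 were chosen after results had been seen. Among genes at least 2-fold changed, the enrichment (hypergeometric test, 773 process terms of 5 to 200 genes, 4974 annotated genes tested as background) called more terms than are described here. Terms left out largely repeat lists of the report, such as iron ion homeostasis in E112K against WT (6 of 10 genes higher, adjusted p = 0.00388) and suppression of ascospore formation in E112K clr6-1 against WT (17 of 21 genes higher, all wtf genes, adjusted p = 4.69e-12). None of the lactate synthesis genes named was in a fixed list, and the other groups below share members with the lists, so they are not independent of them. In E112K against WT, 27 of 181 transmembrane transport genes were higher (11.4 by chance; adjusted p = 0.00475). So were 4 of 5 genes of galactose use, gal1, gal7, gal10 and the assembled transcript MSTRG.5144, and 4 of 5 genes of lactate synthesis from methylglyoxal, hsp3101, hsp3102, hsp3104 and sdj1 (adjusted p = 0.0113 each). Of 5 genes of electron transfer from succinate to ubiquinone 4 were lower, the succinate dehydrogenase genes sdh1, sdh2, sdh3 and sdh4 (adjusted p = 0.000686). Of these, sdh1 fell by 1.05 and sdh2 by 1.46 on the log2 scale. In E112K clr6-1 against WT, 13 of 31 genes of meiotic recombination were higher (2.81 by chance; adjusted p = 0.000398), as were 5 of 7 genes of hydrogen peroxide breakdown (adjusted p = 0.0119) and 18 of 66 genes of carbohydrate metabolism (adjusted p = 0.00265). There 5 of 11 genes of arginine synthesis were lower, aca1, arg12, arg3, arg4 and arg5 (adjusted p = 0.00465). In E112K clr6-1 against E112K, 17 of 21 genes of the term for suppression of ascospore formation were higher, all of them wtf genes (adjusted p = 7.04e-18), and 14 of 52 sporulation genes were higher (2.16 by chance; adjusted p = 5.09e-06).

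Splitting the 6 libraries of a comparison into 3 and 3 gives 10 splits, which cannot give a share under 0.05. The real split called 3914, 4286 and 4035 genes in the 3 comparisons, and the highest of the other splits called 0 with edgeR (91, 49 and 38 at an unadjusted p under 0.05), so 1 split in each comparison, the real one, reached that count. For lists the real split called 13, 16 and 9 and the highest other 17, 16 and 15; 3, 2 and 5 of the 10 splits called as many lists as the real one, the real one included.

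Genes at 0 in every library of a group but well counted elsewhere stood out: 19 genes with a mean of at least 50 counts in another group. A candidate explanation is that the authors' assignment of reads between overlapping genes differed between libraries, since 15 of the 19 overlap another annotated gene (78.9%, against 42.6% of 5109 placed genes; one-sided Fisher's exact p = 0.0014), dam1, bag101 and mug108 among them. Sequence missing from a strain could not be tested, since the genes were selected for having no reads in a group; it stays open, among others for the 4 without an overlapping gene, ura4, mat1-Mc, SPAC4F10.17 and SPCC417.12. The overlap does not settle any single gene, and a strong change in expression stays open, as untested. Reads over these genes would be needed to tell.

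Genes near the ends of chromosomes I and II changed more in E112K: 80 of 114 genes within 100 kb (70.2%) had an absolute log2 fold change of at least 1 against WT, whether or not they passed the test, and 290 of 4015 farther away (7.2%), a ratio of 9.72 (one-sided Fisher's exact p = 3.22e-60). That p-value and the bootstrap intervals below treat genes as independent, which neighbouring genes need not be, and they do not measure the spread between libraries. With an estimated correlation, camera did not call the subtelomeric list (adjusted p = 0.055). Reads shared between annotated near-identical copies do not account for the rise among the 33 of 87 subtelomeric genes without such a copy. Those genes had a median log2 fold change of 2.41 (95% bootstrap interval 1.20 to 3.52), with 29 higher and 4 lower. For the subtelomeric genes with a copy, shared reads stay open, and copies outside the annotated genes of the reference were not searched. Low counts in WT are not decided: the 52 genes with a WT mean of at least 100 counts had a median of 0.91, whose interval of 0.326 to 1.245 includes the bound of 0.5 set for that test. Of these genes 34 were higher and 13 lower. The E112K substitution, strain background and growth state stay open and were not tested.

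M-cell genes were higher in E112K clr6-1 than in E112K, and a difference in mating type between the strains, which the labels do not give, is a candidate explanation. Of 11 mating-type-specific genes 9 lay on the side it would need, but the 6 of 7 M-cell genes that were higher (median log2 fold change 1.01, mfm2 by 224-fold) are the observation that prompted the test, so that the 4 P-cell genes alone could have gone against it, and 3 of them were lower (median -0.41). The neighbours of mat1-Mc, SPBC23G7.10c and mag2, rose by 4.77 and 4.41 on the log2 scale. In E112K against WT they had log2 changes of -0.709 and -1.245. No prediction was made for them, so they are not counted for or against a difference in mating type. On the side of the explanation, mat1-Mc had 0 counts in every E112K library and 1275 to 1578 in E112K clr6-1. Against that, WT had almost no mat1-Mc either, yet the P-cell genes, all 4 of which had risen in E112K (median 0.56), had 2 higher and 1 lower in E112K clr6-1 against WT (median 0.15), with sxa1 at 618, 917 and 632 CPM and map2 at 27.3, 42.3 and 24.2 CPM in WT, E112K and E112K clr6-1. The explanation stays open, as map4 rose, mam3 did not pass, and the higher meiotic genes could go with pheromone genes without a change of mating type.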
